A study of Mus musculus with 4 samples.

How the data were processed

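Cells from mouse prostate tumours of 2 genotypes were profiled by droplet-based single-cell RNA sequencing, with 2 libraries per genotype. Per the labels, both genotypes carry a tamoxifen-inducible, prostate-epithelial Cre and floxed alleles that include Smad4 (DKO), and the second also carries floxed alleles of Pygo2 (TKO). The series design mentions 10 and 17 weeks after tamoxifen, and no label used here ties a library to either. The tumours were dissociated with enzymes, red cells were lysed and dying cells were removed by Annexin V, so the shares of cells describe what survived these steps. Per the labels, the samples carried hashtag antibodies and were combined into a single load. Reads were aligned to mm10 with Cell Ranger 7.0.0 and STAR, per the submitters' processing notes. The deposited values are counts of unique molecular identifiers (UMIs) per gene and cell, whole numbers that are not normalised, per the file headers and the values themselves.

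The files hold 32285 genes and 6 hashtag features, and 32235 gene IDs matched the GENCODE annotation of GRCm38 (mm10), from which positions were taken. Of 3508 barcodes, 3381 were kept with at least 200 genes and at most 20% mitochondrial UMIs. DKO replicates 1 and 2 kept 617 and 759 cells with 9167770 and 14660012 UMIs, and TKO replicates 1 and 2 kept 1208 and 797 cells with 18360201 and 10505183 UMIs. Gene counts differed between every pair of libraries by more than sampling noise (chi-square per degree of freedom 24.2 to 67.2), so none was a copy of another. Scrublet marked 4 cells (0.118%) as doublets, too few to say that doublets were found, and doublets were kept.

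Counts were scaled per cell and log-transformed. Then 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1.0 were used (scanpy 1.11.5, leidenalg 0.10.2). Clusters were named from marker lists fixed before the data were examined. The naming rule was set after the data were seen: a cluster needed at least 3 markers of its class raised by 1.0 on the log2 scale and a score above 0.5. It stayed unnamed where markers of other classes led its top 10 genes, or where its UMIs were low and no own marker was among them. This left 3 clusters unnamed, 2 of which scored highest for neutrophil markers. Unnamed clusters held 21.2% and 9.49% of the cells in the DKO libraries and 15.0% and 9.41% in the TKO libraries. No cluster was named endothelial at these settings, so the planned endothelial comparison has no fit.

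For each class with at least 20 cells in every library, UMI counts were summed per library and tested with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood test, group as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. Standard errors are those that the fitted change and its p-value imply. The 33 gene lists fixed before the data were examined were tested with camera (limma 3.58.1) on log2 CPM (UMIs scaled to a common total per library and class) with a prior count of 2, a preset correlation of 0.01 and at least 4 tested genes, adjusted over lists within a class. Alternatives were an estimated correlation and fry. Shares of cells per class were tested with edgeR on cell numbers with the library total as scaling. The share of T-like cells with a Cd8a or Cd8b1 UMI was compared by an exact two-sided permutation test, for which 2 against 2 libraries allow no p below 0.333. Intervals are exact 95% binomial intervals and cover counting error only. Nothing in the labels used here states that the libraries of a genotype came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

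Named genes followed a rule fixed before the data were examined. It took target genes and genes tied to the model, among them Pygo2, Smad4, Kit, Ido1, Trp53 and Sp1. In each class it took up to 10 genes each way (12 in epithelial-like cells) among those past the threshold with both TKO libraries on one side of both DKO libraries and at least 20 CPM in the higher group, and where fewer than 3 passed, the 5 with the smallest p. It also took up to 4 members with the smallest p from each called list and from the T cell, interferon, antigen presentation and Wnt lists. Predicted genes and Rik clones were left out. The text names part of these, and some results are left out of it.

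The tests were tried on simulated counts with 200 genes changed by known factors. In simulated T- and NK-like cells (11140 genes) 37% of genes changed 2-fold and 90.5% of genes changed 4-fold were recovered. In simulated epithelial-like cells (9768 genes) these shares were 2% and 57%, in macrophage- and monocyte-like cells (7600 genes) 5.5% and 77%, in neutrophil-like cells (7442 genes) 1% and 79%, in fibroblast-like cells (11064 genes) 23% and 74.5%, and in all cells summed (15466 genes) 10% and 77.5%. Unchanged genes were also called: at 2-fold 35 in fibroblast-like, 11 in all cells, 9 in T- and NK-like, 3 in epithelial-like, 3 in macrophage- and monocyte-like and 0 in neutrophil-like cells, and at 4-fold 16, 32, 20, 19, 8 and 12. In most of these simulations false calls were a larger part of all calls than 0.05, so a call at 0.05 carries more risk than that rate. A simulated list shifted in epithelial-like cells was called by camera at the preset correlation and had an adjusted p of 0.33 with an estimated correlation. Its genes were drawn independently, so this does not show how often camera calls unchanged lists of genes that vary together. In 100 simulated draws of cell shares a 2-fold change of a class was called in 27% and a 4-fold change in 87%, and at 4-fold 11.1% of unchanged classes were also called. These draws used a preset spread between libraries, not that of the data. Some classes spread more here, such as epithelial-like cells in DKO (5.67% and 11.6%), so recovery here may be lower. The alternatives tried were other size factors, DESeq2 1.42.0, no low-count filter, other cell filters, doublets left out, other clustering resolutions, a replicate block and leaving out each library in turn.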

Results

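Single-cell transcriptomes were collected from mouse prostate tumours with floxed alleles that include Smad4 (DKO, 2 libraries) and from tumours with the same alleles plus floxed Pygo2 (TKO, 2 libraries). The comparison asks what loss of Pygo2, a chromatin reader that acts with beta-catenin in Wnt signalling, changes in the tumour and its immune cells. The median depth was 8404 and 10310 UMIs per cell in DKO replicates 1 and 2 and 9115.5 and 8977 in TKO replicates 1 and 2. Most cells were immune. Neutrophil-like cells and T- and NK-like cells were the largest classes, and epithelial-like cells numbered 35 and 88 in the DKO libraries and 52 and 26 in the TKO libraries.

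Pygo2 transcript (ENSMUSG00000047824, mm10 chromosome 3, 89430214 to 89435128) was measured first, since its allele separates the groups. In epithelial-like cells it gave 10 and 33 UMIs in the DKO libraries and 25 and 4 in the TKO-labelled libraries, a log2 fold change of 0.55 ± 0.54 (SE, n = 2 per group, edgeR adjusted p = 0.86). Without TKO replicate 1 the change was -0.42. Smad4 (ENSMUSG00000024515, chromosome 18, 73639009 to 73703780), floxed in both genotypes, differed by -0.26 ± 0.23 on the log2 scale and did not pass (edgeR adjusted p = 0.85). The deleted exons and the position of the sequenced 3-prime tag within them are not given in the sources used here, so a kept signal checks neither the deletion nor the labels. Groups below are those of the labels. Among other genes tied to this model, the receptor gene Kit differed by -0.79 ± 0.47, Ido1, which starts tryptophan breakdown, by -1.41 ± 0.84, Trp53 by -0.06 ± 0.38 and Sp1 by -0.06 ± 0.29. None passed in the edgeR test. Ido1 had 0 UMIs in TKO replicate 2, and its change was -7.71 without TKO replicate 1 and -0.78 without TKO replicate 2.

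Epithelial-like cells made up 5.67% and 11.6% of cells in the DKO libraries and 4.30% and 3.26% in the TKO libraries (means 8.63 ± 4.19% and 3.78 ± 0.74%, SD, n = 2). T- and NK-like cells made up 18.5% and 30.3% against 29.8% and 38.9%, neutrophil-like cells 34.7% and 29.4% against 28.1% and 27.9%, and mast-like cells 0.81% and 0.79% against 1.66% and 1.63%. With the 2 unnamed clusters that scored as neutrophil put back, neutrophil-like cells made up 54.3% and 37.8% against 41.9% and 34.6%. None of the 8 classes passed. The TKO over DKO ratio of shares was 0.44 for epithelial-like cells (log2 -1.19 ± 0.45, edgeR adjusted p = 0.31), 1.40 for T- and NK-like cells (0.48 ± 0.32, adjusted p = 0.36) and 2.04 for mast-like cells (1.03 ± 0.26, adjusted p = 0.23, from 5, 6, 20 and 13 cells). At a clustering resolution of 2.0 the mast-like class held only 2, 2, 7 and 3 cells, with a ratio of 1.67 (log2 0.74 ± 0.74). A further 3, 4, 13 and 10 cells then formed an unnamed cluster led by Csf2, Il5, Calca and Il13, so the name mast-like is uncertain for most of the class. At that resolution the epithelial ratio was 0.23 and passed (edgeR adjusted p = 0.015). The class then held only the basal keratin cluster (Krt5, Krt14), with 19 and 38 cells in DKO and 16 and 3 in TKO. Unnamed cells then made up 24.3% and 16.9% in DKO and 18.8% and 13.9% in TKO. That ratio therefore covers only a part of the epithelial-like cells. At resolution 1.0 without DKO replicate 2 the epithelial ratio was 0.68.

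Cytotoxic T cells carry CD8. The share of T-like cells with a Cd8a or Cd8b1 UMI was 18.9% (95% interval 11.6 to 28.3%) and 29.6% (22.8 to 37.1%) in the DKO libraries and 42.9% (37.2 to 48.8%) and 31.1% (25.4 to 37.2%) in the TKO libraries. The means were 24.3 ± 7.52% and 37.0 ± 8.36% (SD, n = 2), a difference of 12.7 percentage points. The exact permutation p was 0.333, the smallest that 4 libraries allow. Neutrophil-like cells, which should lack CD8, had such a UMI in 2.25% to 3.14% of cells at median depths of 5967.5 to 7172.5 UMIs, against 9985 to 12277 in T-like cells. With each cell thinned to 1000 UMIs, no cell was left out. The shares were then 7.37% and 16.0% in DKO and 20.9% and 16.7% in TKO, a difference of 7.17 points. Thinning lowered the share in every library, so these points cannot be set against the 12.7 points at full depth. Without TKO replicate 1 the difference at full depth was 6.81 points. The share of T-like cells with a UMI of Foxp3, the regulatory T cell factor, was 25.3% and 20.1% in the DKO libraries and 15.9% and 9.16% in the TKO libraries, a comparison added after the data were seen (exact permutation p = 0.333). In neutrophil-like cells the Foxp3 share was 0.45% to 1.35%, and the Foxp3 shares were not thinned.

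**Figure D1:**
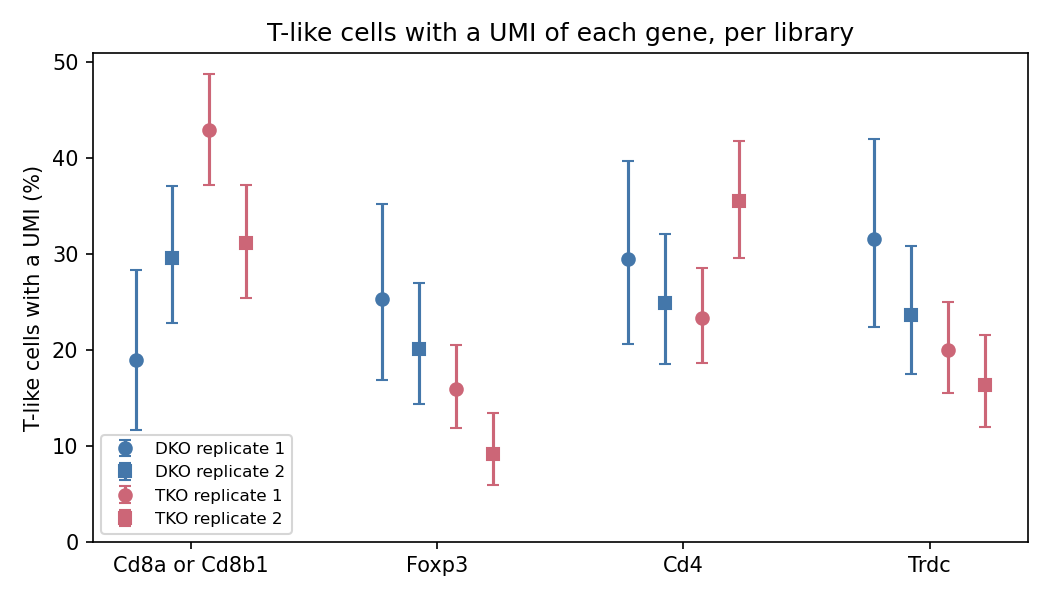
Percent of T-like cells with at least 1 UMI of each gene (vertical axis) in each library, with exact 95% binomial intervals as bars, blue for DKO and red for TKO. Foxp3 and Trdc shares are lower in both TKO libraries than in either DKO library, the CD8 share is higher in both, and the Cd4 shares overlap.

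In T- and NK-like cells 3 genes of 11140 passed. Cpm (ENSMUSG00000020183, chromosome 10, 117629500 to 117687352), which encodes the surface enzyme carboxypeptidase M, rose from 20.7 and 15.9 CPM in the DKO libraries to 102 and 82.1 in the TKO libraries (log2 fold change 2.38 ± 0.22, SE, n = 2 per group, edgeR adjusted p = 0.023). Gpr55 (ENSMUSG00000049608, chromosome 1, 85938318 to 85961007), a lipid-sensing receptor, fell from 44.4 and 37.0 to 6.04 and 3.15 CPM (-3.08 ± 0.32, adjusted p = 0.024, and -3.67 without TKO replicate 1). Gpr55 was also lower in neutrophil-like (-2.96) and dendritic-like cells (-0.96) at an unadjusted edgeR p under 0.05. Olfr1369-ps1 (chromosome 13, 21111483 to 21119095) fell from 39 and 69 UMIs to 2 and 5 (adjusted p = 0.024). It is uncertain, since it belongs to the olfactory receptor family and may share reads with relatives. The edgeR test gave 599 genes at an unadjusted p under 0.05, DESeq2 called 28, and without TKO replicate 1 edgeR called 0.

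Genes of regulatory T cells were lower as a group in the TKO T- and NK-like cells, where all 9 tested had a negative change (median log2 -0.40, camera adjusted p = 0.00057). That call had adjusted p = 0.87 with an estimated correlation, and 0.082 without DKO replicate 1 and 0.064 without TKO replicate 2. Adjusted over the list alone, 3 fell, and over all genes tested 0 did: the Ikaros-family factor gene Ikzf4 (-1.02 ± 0.18), Il2ra, a chain of the interleukin-2 receptor (-1.03 ± 0.21), and Ikzf2 (-0.40 ± 0.13), which is also among the leading genes of the Foxp3 cluster. The class held 114 and 230 cells in the DKO libraries and 360 and 310 in the TKO libraries. Of these the Foxp3 cluster held 28 and 36 against 45 and 24, and the CD8 cluster 14 and 36 against 110 and 58. Within the class the Foxp3 cluster was a smaller part, and the CD8 cluster a larger part, in both TKO libraries than in either DKO library. Neither cluster's share of all retained cells passed (edgeR adjusted p = 0.52 and 0.37), but that is not the share within the class. Shares within the class were not tested. The smaller Foxp3 cluster goes the same way as the fall of the regulatory T cell list. How much of that fall the makeup of the class accounts for cannot be told. Of the cytotoxic effector genes, 4 of 16 rose and 1 fell adjusted over the list alone, with 0 over all genes tested. The list was not called (camera adjusted p = 0.19). They include the granzyme genes Gzmk (1.29 ± 0.27) and Gzma (0.77 ± 0.21), the perforin gene Prf1 (0.97 ± 0.29) and, downward, the activating receptor gene Klrk1 (-0.49 ± 0.16). Gzmk, Gzma and Prf1 also lead clusters within the class. Without DKO replicate 2 Prf1 was at 1.72 and Mcm6, an S phase gene, at 1.247. Division genes were higher, 18 of 19 for G2 and M phase (camera adjusted p = 2.9e-05, and adjusted p = 0.87 with an estimated correlation). Without DKO replicate 1, which held 0 cells of the cycling cluster against 7, 10 and 11 in the others, the camera adjusted p was 0.65. S phase genes were higher in 18 of 20 (camera adjusted p = 0.0013, adjusted p = 0.87 with an estimated correlation), such as Mcm6 (0.62 ± 0.29), with a camera adjusted p of 0.97 without DKO replicate 1. TGF-beta and BMP targets were lower in 12 of 12 (camera adjusted p = 0.032, adjusted p = 0.87 with an estimated correlation), such as Smad7 (-0.31 ± 0.14), with a camera adjusted p of 0.36 without DKO replicate 1. No member of these 3 lists passed adjusted over the list alone. Monocyte markers in this class stood at 788 and 736 CPM in the DKO libraries and 500 and 477 in the TKO libraries.

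**Figure D2:**
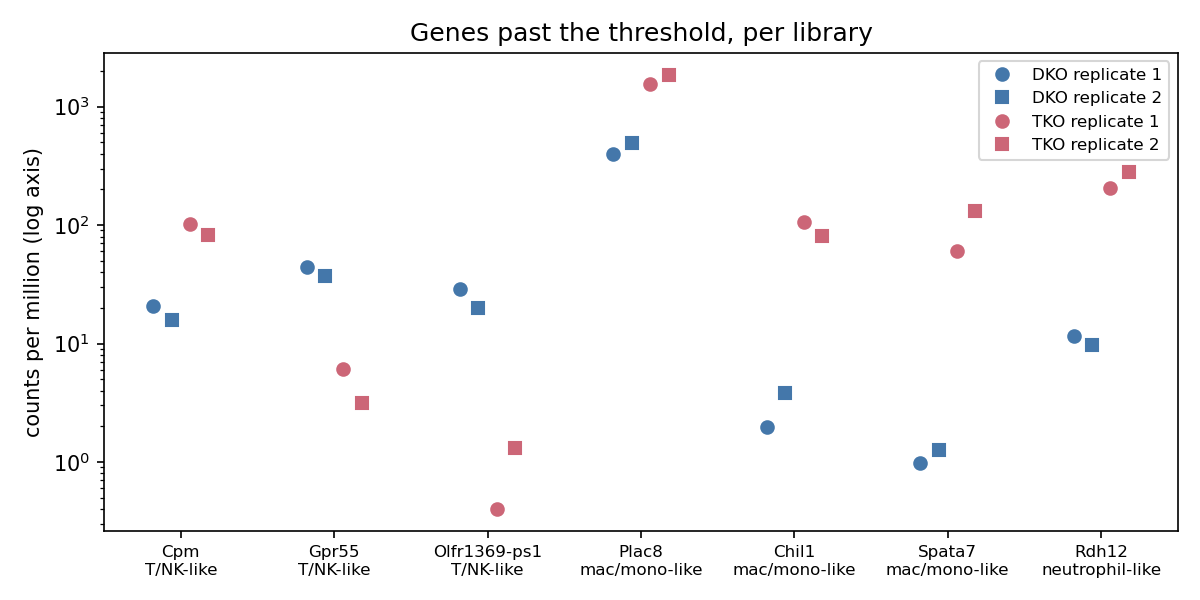
CPM on a log axis for the genes that passed the edgeR test in T- and NK-like, macrophage- and monocyte-like and neutrophil-like cells, 1 point per library, blue for DKO and red for TKO. Both libraries of a group lie on the same side for each gene, with Plac8 at 401 and 490 in DKO and 1548 and 1857 in TKO.

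In macrophage- and monocyte-like cells 3 genes of 7600 passed, all higher in TKO. Plac8 (ENSMUSG00000029322, chromosome 5, 100553725 to 100572245), a monocyte marker, rose from 401 and 490 to 1548 and 1857 CPM (log2 fold change 1.93 ± 0.22, SE, n = 2 per group, edgeR adjusted p = 0.040). Chil1 (ENSMUSG00000064246, chromosome 1, 134182176 to 134190181), a chitinase-like secreted protein, rose from 1.96 and 3.81 to 106 and 80.4 CPM (5.03 ± 0.45, adjusted p = 0.020). Spata7 (chromosome 12, 98628157 to 98669815) rose from 2 UMIs in the DKO libraries to 217 in the TKO libraries, a ratio of 73.5 (95% counting interval 20.1 to 610). At an unadjusted edgeR p under 0.05 Spata7 was also higher in T- and NK-like (log2 3.41) and dendritic-like cells (5.46). So was Chil1 in fibroblast-like (2.69) and neutrophil-like cells (0.80). The edgeR test gave 523 genes at an unadjusted p under 0.05 and DESeq2 called 37. The class held 20 and 15 macrophage-cluster cells of 35 and 33 in the DKO libraries and 25 and 4 of 76 and 42 in the TKO libraries, and macrophage markers stood at 26779 and 25761 CPM in DKO and 18596 and 8968 in TKO. Monocyte markers, a list that includes Plac8, overlapped, at 11750 and 8976 CPM in DKO and 9618 and 11155 in TKO.

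Macrophage-cluster cells were a smaller part of the macrophage- and monocyte-like class in both TKO libraries than in either DKO library. The lists were not refitted within its clusters, so that mix may be part of the changes that follow. Genes of immunosuppressive myeloid cells were lower as a group in the same class, 12 of 14 tested (median log2 -0.57, camera adjusted p = 0.0058, and adjusted p = 0.78 with an estimated correlation). Adjusted over the list alone 3 fell, against 0 over all genes tested: Ptgs2, the inducible prostaglandin synthase (-1.10 ± 0.23), Cd274, the PD-L1 gene (-1.22 ± 0.28), and Hmox1, haem oxygenase (85.1 and 98.9 CPM in DKO, 41.5 and 51.7 in TKO). Ptgs2 was lower in all 6 classes compared, from -1.52 in epithelial-like to -0.41 in fibroblast-like cells. In 4 of them its unadjusted edgeR p was under 0.05, so its fall was not particular to this class. The list's camera adjusted p was 0.098 without DKO replicate 1 and 0.060 without TKO replicate 1. Genes induced by interferon gamma were not called (camera adjusted p = 0.14), and 3 fell adjusted over the list alone, 0 over all genes tested, including Gbp5 (-2.20 ± 0.48) and the chemokine gene Cxcl10 (-1.38 ± 0.38). Gbp5 was at -1.46 without TKO replicate 1 and -2.92 without TKO replicate 2. Type I interferon genes moved both ways, with 4 higher and 3 lower adjusted over the list alone and 0 over all genes tested, such as Ifih1 (1.19 ± 0.30) and Rsad2 (-1.78 ± 0.37). The list was not called (camera adjusted p = 0.086). TGF-beta target genes were lower in 10 of 12 (camera adjusted p = 0.0099, adjusted p = 0.78 with an estimated correlation, 0 adjusted over the list alone). Without TKO replicate 1 the camera adjusted p was 0.11. Hypoxia and glycolysis genes were lower in 15 of 17, such as Hk2 (-0.63 ± 0.27; camera adjusted p = 0.026, adjusted p = 0.83 with an estimated correlation, 0 adjusted over the list alone). Without DKO replicate 1 the camera adjusted p was 0.95.

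In neutrophil-like cells 1 gene of 7442 passed. Rdh12 (ENSMUSG00000021123, chromosome 12, 79208914 to 79222665), a retinol dehydrogenase, rose from 11.7 and 9.65 to 204 and 278 CPM (log2 fold change 4.48 ± 0.34, SE, n = 2 per group, edgeR adjusted p = 0.0063). Rdh12 is also among the leading genes of the largest neutrophil cluster, which held 93 and 119 cells in the DKO libraries and 91 and 117 in the TKO libraries. Next by p, and not passing, were the interferon-inducible Ifi202b (-4.02 ± 0.45, adjusted p = 0.064), the ion exchanger gene Slc24a3 (-3.36 ± 0.43), the chitinase-like Chil3 (-4.72 ± 0.63) and the heat shock gene Hspa1a (3.64 ± 0.50). Without TKO replicate 1 Chil3 was at -6.95, Slc24a3 at -4.22 and Hspa1a at 2.83, and without TKO replicate 2 Chil3 was at -4.05. There were 355 genes at an unadjusted p under 0.05 in edgeR, DESeq2 called 19, and leaving out a library gave 29 to 42.

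Granule genes of neutrophils fell as a group in TKO, 8 of 10 tested (median log2 -0.80, camera adjusted p = 1.6e-05). The call was kept without each library in turn (camera adjusted p up to 0.029), with adjusted p = 0.65 with an estimated correlation. There were 7 that fell adjusted over the list alone, and 0 over all genes tested. Examples are the collagenase gene Mmp8 (-2.83 ± 0.44, and -3.49 without TKO replicate 2), the iron-binding Lcn2 (-1.50 ± 0.25) and S100a9, a subunit of calprotectin (-0.80 ± 0.26). Markers of neutrophils stood at 121094 and 105564 CPM in DKO and 90305 and 81361 CPM in TKO, monocyte markers at 12262 and 11124 against 9163 and 7557, and dendritic markers at 596 and 450 against 1013 and 789. Mmp8 and S100a9 also lead a neutrophil cluster found at a clustering resolution of 2.0, with 37 and 38 cells in the DKO libraries and 21 and 21 in the TKO libraries. Genes of chemokines and other factors that recruit myeloid cells were lower in 13 of 15 (camera adjusted p = 0.045, adjusted p = 0.65 with an estimated correlation). The growth factor gene Csf3 was at -1.93 ± 0.53 (-2.51 without DKO replicate 1 and -0.90 without DKO replicate 2), and no member passed adjusted over the list alone. That call was lost without DKO replicate 1 (camera adjusted p = 0.17), without DKO replicate 2 (adjusted p = 0.051) and without TKO replicate 2 (adjusted p = 0.37). TNF and NF-kB genes were lower in 15 of 19, such as Ier3 (-0.57 ± 0.24), and type I interferon genes were higher in 15 of 20, such as Bst2 (0.77 ± 0.28). Both lists had a camera adjusted p of 0.045, with 0 genes adjusted over the list alone. With an estimated correlation they had adjusted p = 0.65 and adjusted p = 0.98. The TNF and NF-kB call was lost whichever library was left out, and the type I interferon call was lost without TKO replicate 2.

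In epithelial-like cells 0 genes of 9768 passed in edgeR, with 555 at an unadjusted p under 0.05, while DESeq2 called 40. The edgeR test called 90 without TKO replicate 1. The smallest p-values belonged to the endothelial adhesion gene Pecam1 (3.46 ± 0.42), Serpinb1a, a protease inhibitor (-2.31 ± 0.29), Spink8 (4.35 ± 0.60), Ifi203 (-3.05 ± 0.42) and Cacna2d3, with 112 UMIs in DKO and 3 in TKO. Each had an edgeR adjusted p of 0.44. Without TKO replicate 1 Spink8 was at 3.74, Ifi203 at -3.85 and the keratin gene Krt6a at -3.72. Squamous genes were lower as a group (camera adjusted p = 0.017, and adjusted p = 0.85 with an estimated correlation). Adjusted over the list alone 3 fell, against 0 over all genes tested: the desmosome gene Dsg3 (-1.24 ± 0.30), the keratin gene Krt6a (-2.53 ± 0.59) and Sprr1b, with 61 UMIs in DKO and 1 in TKO. The camera adjusted p was 0.075 without DKO replicate 1. Hypoxia and glycolysis genes were lower in 15 of 18 (camera adjusted p = 0.0021, adjusted p = 0.85 with an estimated correlation), such as Gapdh (-0.87 ± 0.29) and Egln3 (-0.81 ± 0.28). The camera adjusted p was 0.12 without DKO replicate 2 and 0.097 without TKO replicate 1. Oxidative phosphorylation genes were lower in 22 of 22 (camera adjusted p = 0.0002, adjusted p = 0.85 with an estimated correlation), and the camera adjusted p was 0.055 without TKO replicate 2. Dissociation stress genes were higher in 19 of 19 (camera adjusted p = 0.0053, adjusted p = 0.85 with an estimated correlation), with Jun at 1.02 ± 0.36 and a camera adjusted p of 0.63 without TKO replicate 2. Ribosomal protein genes were lower in 22 of 22, such as Rplp1 (-0.50 ± 0.37; camera adjusted p = 0.0099, adjusted p = 0.85 with an estimated correlation). The camera adjusted p was 0.95 without TKO replicate 2. Matrix genes were lower in 10 of 10 (camera adjusted p = 0.029, adjusted p = 0.85 with an estimated correlation), but Fn1 stood at 297 CPM in DKO replicate 2 against 16.2 to 21.5 in the others, and without that library the camera adjusted p was 0.50. No member of these 5 lists passed adjusted over the list alone. Wnt targets were not called (camera adjusted p = 0.42), with Rnf43, a Wnt receptor ligase, at 1.53 ± 0.47 (0.91 without TKO replicate 2), nor were the antigen presentation genes, with H2-D1 at -0.52 ± 0.33 and reads shared among its near-identical relatives. At a clustering resolution of 2.0 the basal keratin cluster (Krt5, Krt14) held 19 and 38 cells in DKO and 16 and 3 in TKO, and the lists were not refitted within it. The gene fit within it called 0 of 8610 genes in edgeR, and the change of Dsg3 there was positive. Median depth per epithelial-like cell was 20132 and 21763.5 UMIs in DKO and 10172.5 and 8202 in TKO. In this class T cell markers stood at 37.6 and 115 CPM in DKO and 165 and 291 in TKO, endothelial markers at 50.1 and 68.6 against 109 and 201, NK cell markers at 83.3 and 65.9 against 153 and 210, and smooth muscle markers at 85.1 and 319 against 47.3 and 41.6.

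In fibroblast-like cells 0 genes of 11064 passed in edgeR, with 422 at an unadjusted p under 0.05, while DESeq2 called 9 and edgeR called 24 without DKO replicate 2. Closest were Plet1 (-3.10 ± 0.28) and the mesothelial gene Msln (-4.32 ± 0.40), each with an edgeR adjusted p of 0.069. MHC class II genes were lower in 7 of 7 (median log2 -1.19, camera adjusted p = 4.1e-06, and adjusted p = 0.81 with an estimated correlation). The call was kept without each library in turn. Of these, 6 fell adjusted over the list alone, against 0 over all genes tested, among them Cd74, the invariant chain gene (-1.21 ± 0.38), and H2-Aa (-1.46 ± 0.48), and both also lead the largest dendritic cluster. Monocyte markers in the class stood at 3813 and 2876 CPM in DKO and 2628 and 1869 in TKO, and plasma cell markers at 248 and 11924 against 209 and 206. Smooth muscle markers stood at 1801 and 870 CPM against 766 and 495, and epithelial markers at 1025 and 397 against 325 and 259. Endothelial markers lay the other way, at 664 and 783 CPM in DKO and 1008 and 921 in TKO. Dendritic markers (1355 and 1518 against 1376 and 1403) and macrophage markers (2879 and 3188 against 3053 and 3068) overlapped between the groups. Fibrillar collagen and matrix genes were lower in 15 of 17 (camera adjusted p = 0.00057, adjusted p = 0.81 with an estimated correlation), such as Col5a1 (-0.44 ± 0.18), with 0 adjusted over the list alone and a camera adjusted p of 0.37 without TKO replicate 2. S phase genes were higher in 16 of 18 (camera adjusted p = 0.019, adjusted p = 0.92 with an estimated correlation, 0 adjusted over the list alone), with Clspn at 1.40 ± 0.74 and a camera adjusted p of 0.89 without DKO replicate 1. Clspn was at 0.74 without DKO replicate 1 and 3.25 without DKO replicate 2, and H2-Aa at -2.31 without TKO replicate 2. Wnt targets were not called (camera adjusted p = 0.17), and 1 of 13, the feedback inhibitor gene Nkd1 (1.42 ± 0.32), rose adjusted over the list alone, against 0 over all genes tested.

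With all cells of a library summed, 0 genes of 15466 passed in edgeR, with 1830 at an unadjusted p under 0.05, while DESeq2 called 352 and edgeR called 113 without DKO replicate 1. These sums mix the makeup of a library with expression within its cells. The smallest p-values belonged to Dscaml1 (5.32 ± 0.34), the small proline-rich gene Sprr2d (-3.74 ± 0.26), Ctse, cathepsin E (1.75 ± 0.13), Rdh12 (3.52 ± 0.28) and the platelet chemokine gene Ppbp (-4.62 ± 0.37), each with an edgeR adjusted p of 0.14. Cytotoxic effector genes were higher in 16 of 16 (camera adjusted p = 1.8e-06, and adjusted p = 0.68 with an estimated correlation). Adjusted over the list alone 6 rose, against 0 over all genes tested, among them Gzmk (1.77 ± 0.22) and Ccl5 (0.77 ± 0.16). Checkpoint genes were higher in 10 of 12 (camera adjusted p = 0.0039, adjusted p = 0.68 with an estimated correlation), with 5 adjusted over the list alone and 0 over all genes tested, such as Pdcd1, the PD-1 gene (0.92 ± 0.13). Luminal progenitor genes were lower in 10 of 10 (camera adjusted p = 1.2e-05, adjusted p = 0.68 with an estimated correlation), with 6 adjusted over the list alone and 0 over all genes tested, such as Krt7 (-2.93 ± 0.47, and -3.74 without TKO replicate 1). The 15 called lists also include squamous genes, lower in 11 of 13 (camera adjusted p = 0.00016, Krt6a -3.43 ± 0.48, and -4.21 without TKO replicate 1), hypoxia genes, lower in 17 of 18 (4.1e-05, Egln3 -1.02 ± 0.14), and granule genes, lower in 9 of 9 (0.0015, Lcn2 -1.32 ± 0.16), each with adjusted p = 0.68 with an estimated correlation. Of these genes 5, 3 and 3 fell adjusted over the list alone, against 0 over all genes tested. These 6 calls were kept without each library in turn, as were those of the naive and memory T cell genes (camera adjusted p = 0.0013, Ccr7 0.58 ± 0.12) and the matrix genes (4.9e-05, Col1a1 -0.54 ± 0.13), each with adjusted p = 0.68 with an estimated correlation. Adjusted over the list alone 6 naive and memory genes rose and 0 matrix genes passed, against 0 over all genes tested. The other 7 of the 15 were lost without a library. Luminal genes (camera adjusted p = 0.0032) had 0.073 without TKO replicate 1, and basal genes (0.0059) had 0.20 and MHC class II genes (0.0038) had 0.15 without DKO replicate 2. MHC class I genes (0.040), S phase genes (0.00051) and G2 and M phase genes (0.0032) had 0.62, 0.62 and 0.25 without DKO replicate 1. Genes induced by interferon gamma (0.032) had 0.61 without TKO replicate 2. With an estimated correlation these 7 had adjusted p = 0.68 or adjusted p = 0.75.

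The Ifi200 family of interferon-inducible DNA sensors on chromosome 1 differed between the groups in several classes at an unadjusted p under 0.05. Ifi202b was at -4.02 ± 0.45 in neutrophil-like, -5.30 ± 0.93 in macrophage- and monocyte-like and -2.71 ± 0.66 in T- and NK-like cells, and at -0.23 ± 0.54 in epithelial-like cells (log2, SE, n = 2 per group). These members are near-identical and their reads can be shared, so single values are uncertain.

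**Figure D3:**
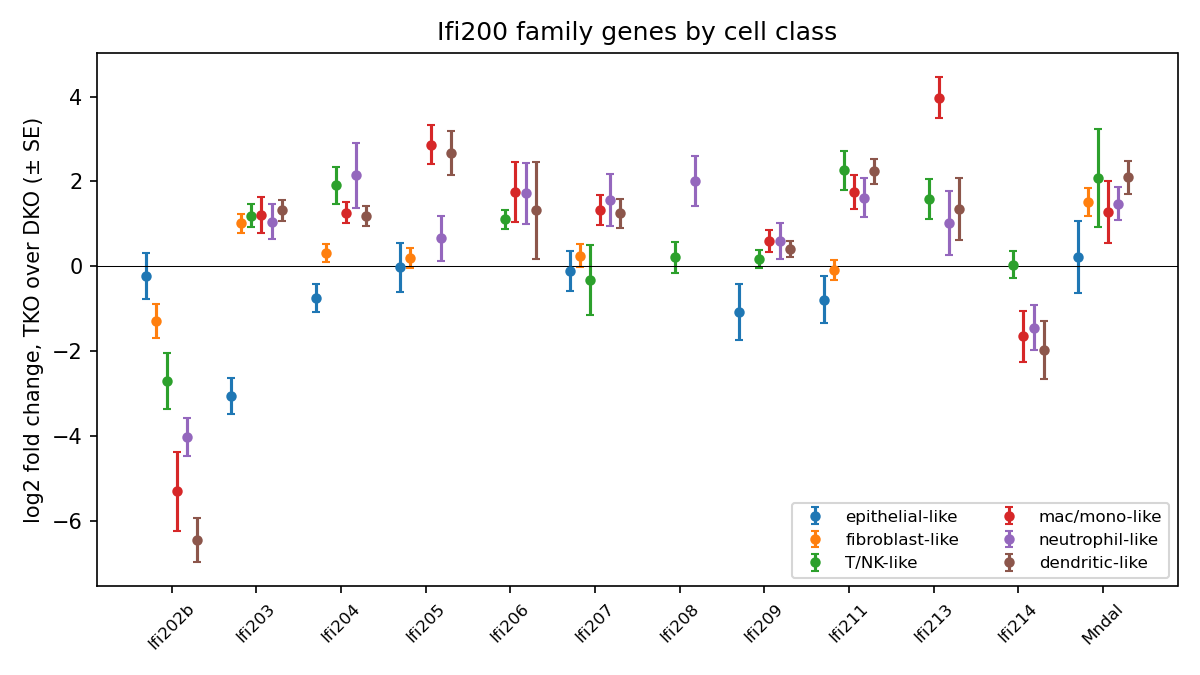
Log2 fold change of Ifi200 family genes, TKO over DKO, with standard errors as bars, by cell class. Ifi202b lies below 0 in every class while most other members lie above 0 outside epithelial-like cells.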

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

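All tests of explanations in this part were chosen after the results they bear on had been seen.

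Differences of the TKO effect between cell classes were tested as an interaction in edgeR, adjusted at 0.05, and this comparison was added after the data were seen. Plac8 was higher in TKO in macrophage- and monocyte-like cells and lower in T- and NK-like cells, a difference of 2.94 on the log2 scale (edgeR adjusted p = 0.0036). Rdh12 differed by 3.94 between neutrophil-like and T- and NK-like cells, and Slc24a3 by -5.03. Chil1 in neutrophil-like cells differed from macrophage- and monocyte-like cells by -4.22, and Hspa1a in fibroblast-like cells differed from neutrophil-like cells by -4.14. Pecam1 differed by -3.26 between T- and NK-like and epithelial-like cells and by -4.94 between neutrophil-like and epithelial-like cells. Klrd1, a natural killer receptor gene, differed by -3.65 between T- and NK-like and epithelial-like cells, where NK cell markers stood at 83.3 and 65.9 CPM in DKO and 153 and 210 in TKO. Ifi202b differed from its change in epithelial-like cells by -3.86 in neutrophil-like and -6.29 in dendritic-like cells, and from fibroblast-like cells by -5.12 in dendritic-like cells.

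Hashtags A0307 and A0308, which no sample here carries, gave 14307 and 14414 UMIs over the 4 libraries, with a median of 3 to 4 per cell, and the labelled hashtag was the highest in every cell.

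Genes of the interferon-inducible Ifi200 family on chromosome 1 (173468485 to 174031810) differed between the groups in several classes, 8 of 11 tested against 0.678% of genes elsewhere, though near-identical members can share reads. Ifi202b fell by more than 2 SE in 4 of the 4 classes where the family sum was higher by more than 1 on the log2 scale. This argues against an interferon response for that gene. The family sum differed by more than 0.5 on the log2 scale with the libraries apart in 5 of 6 classes (upward in 4, downward in epithelial-like cells). That argues against reads moved between members alone. Reads left uncounted, as where they match several members, would change the sum, and this was not tested. For the members that rose, an interferon response stays open, since interferon genes outside the locus had medians from 0.13 in neutrophil-like to 0.67 in dendritic-like cells against family sums higher by 1.04 to 1.55. The DKO libraries also differed from each other at the locus in some classes. In neutrophil-like cells the family sum was 540 and 163 CPM in DKO and 1014 and 1047 in TKO. In T- and NK-like cells Mndal was at 118 and 13.3 CPM in DKO and 249 and 245 in TKO. In macrophage- and monocyte-like cells the DKO sums lay closer, at 770 and 609 CPM. The cause of this spread within a labelled genotype was not tested. A strain variant may also be the cause of the group difference and cannot be told apart from genotype. Genes within 20 Mb were not enriched (Fisher's exact p = 0.331), while chromosome 1 with only the locus left out held 1.95% against 0.599% elsewhere (Fisher's exact p = 0.0013). Gpr55, Chil1, Ctse and Ptgs2 were among those chromosome 1 genes, so the same limit holds for them. On other chromosomes 54 of 9017 genes also changed in several classes, such as Spata7 on chromosome 12. Strain cannot be told apart from genotype for genes on other chromosomes either. An effect of Pygo2 loss itself stays open as well and was not tested.

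Plac8, Chil1 and Spata7 rose in TKO in a class in which 20 of 35 and 15 of 33 cells in DKO and 25 of 76 and 4 of 42 cells in TKO were macrophage-like. Within the monocyte-like cluster alone (15, 18, 51 and 38 cells) the log2 ratio of Plac8 was 1.248 against 1.93 in the class, and those of Chil1 and Spata7 were 5.12 and 5.34 against 5.03 and 6.26, ratios set largely by a pseudocount of 1 CPM, since the DKO libraries held 2 and 0 UMIs of Chil1 (206 and 54 in TKO) and 1 and 0 of Spata7 (52 and 91 in TKO). The mix alone is argued against for Chil1 and Spata7, whose UMIs stayed apart between the groups within that cluster. Both genes were also higher in other classes, so their rise was not particular to this one. For Plac8 (962 and 993 against 2503 and 2142 CPM in the cluster) the mix may be part of the class difference, and how large a part cannot be told. A biological effect of the genotype stays open and untested.

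Seminal vesicle genes, a marker list fixed before the data were examined, stood at 100851 CPM in the epithelial-like cells of TKO replicate 1 and at 135, 41.7 and 65.1 CPM in the other libraries. Neutrophil-like cells of that library stood at 1.00 times and T- and NK-like cells at 0.86 times the highest other library. These ratios cannot weigh free RNA, since the samples shared a single load and its free RNA would reach every library. A few cells of another tissue may be the source, since 1 cell of 52 held 95% of these UMIs, which free RNA spread over the cells would not give. The unnamed cluster that scored highest for these markers held 10 and 8 cells in the DKO libraries and 14 and 21 in the TKO libraries. No biological explanation was tested.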

How the results depend on the processing

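The added alternatives (T-like or NK-like cells alone, the cycling cluster left out, T cell shares other than CD8) were chosen after seeing the data. Of the counts, share ratios and targets under alternatives other than leaving out a library, 152 were kept, 31 moved, 1 became stronger and 1 changed sign. Median-of-ratios size factors left the gene counts of the planned classes and of all cells unchanged. Without a low-count filter edgeR called 247 genes in epithelial-like, 147 in T- and NK-like, 196 in macrophage- and monocyte-like, 65 in neutrophil-like and 179 in fibroblast-like cells and 276 in all cells, and DESeq2's Wald test called 40, 28, 37, 19, 9 and 352. The strict cell filter left 1 in macrophage- and monocyte-like cells. NK-like cells alone, with 19 cells in DKO replicate 1, gave 1 gene and T- and NK-like cells without the cycling cluster gave 8 (9 with median-of-ratios size factors). T-like cells alone gave 3 genes, and 51 to 277 without a library. Leaving out each library in turn gave 0 to 90 genes in epithelial-like, 0 to 65 in T- and NK-like, 3 to 134 in macrophage- and monocyte-like, 29 to 42 in neutrophil-like and 0 to 24 in fibroblast-like cells and 0 to 113 in all cells, where the lone library of a group is assumed to vary like the pair. Of the gene lists, camera called 8 to 12 in epithelial-like, 0 to 12 in T- and NK-like, 0 to 10 in macrophage- and monocyte-like, 1 to 4 in neutrophil-like and 1 to 8 in fibroblast-like cells without a library, and 0 were called in any of these classes or in all cells with an estimated correlation or by fry. The self-test's shifted list was also missed with an estimated correlation, so that setting has little power here. Fry was not tried in the self-test. The self-test's genes were drawn independently, so it cannot tell whether the preset correlation overcalls lists of genes that vary together. The epithelial-like share ratio was 0.23 at a Leiden resolution of 2.0, where the class held only the basal keratin cluster, with 3 cells in TKO replicate 2. Some values changed sign, and the cause was not tested. At that resolution Smad4 was 0.56, Kit 0.093 and Dsg3 0.11 in the smaller epithelial-like class, a different set of cells from the main one. Trp53 was 0.11 with the strict cell filter and -0.43 to 0.45 without a library, Sp1 was 0.0584 without a cell filter and -0.19 to 0.0636 without a library, and Pygo2 was -0.42 to 0.95 without a library. The difference in Cd4 share was -3.85 to 8.30 points. Lists that changed direction without a library were matrix genes in epithelial-like cells (camera adjusted p 9.7e-21 to 0.50), type I interferon in neutrophil-like cells (8.1e-09 to 0.33), S phase in fibroblast-like cells (2.8e-07 to 0.89) and G2 and M phase in all cells (1.9e-13 to 0.25). Replicate numbers are not stated to pair the libraries. The deviations of same-numbered libraries correlated at 0.41 in neutrophil-like cells, and at only -0.04 to 0.15 in the other classes and in all cells. With the replicate block, edgeR called 16 genes in T- and NK-like, 24 in macrophage- and monocyte-like and 81 in neutrophil-like cells, 6 in all cells, 222 in T-like cells alone, 24 in dendritic-like cells, and 1 in neutrophil-like cells with the unnamed neutrophil-scoring clusters put back. Trp53 with the block was 0.0258 in epithelial-like cells. An endothelial class was named only without a cell filter, with 13 cells (4, 2, 3 and 4 per library) and a share ratio of 0.833 (edgeR adjusted p = 0.73), so its gene fits were not run.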

Other observations

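Dendritic-like cells were fitted after the data were seen. They numbered 41 and 55 in the DKO libraries and 99 and 64 in the TKO libraries, and 3 genes of 9074 passed. Il12b, which encodes a subunit of interleukin-12, rose from 4.39 and 1.27 to 71.3 and 60.1 CPM (log2 fold change 4.63 ± 0.43, SE, n = 2 per group, edgeR adjusted p = 0.0097). Il12b was at 5.64 without DKO replicate 1 and 3.89 without DKO replicate 2. Ppfia4 fell from 39.5 and 40.5 to 0.72 and 1.19 CPM (edgeR adjusted p = 0.0054), and Ifi202b fell from 182 UMIs to 3, a ratio of 102 (95% counting interval 34.4 to 500). The edgeR test gave 642 genes at an unadjusted p under 0.05 and DESeq2 called 33. At the other clustering resolutions, where the class held 98 cells in TKO replicate 1, edgeR called 6. Leaving out a library gave 105 (DKO replicate 1), 75 (DKO replicate 2), 20 (TKO replicate 1) or 5 (TKO replicate 2).

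Type I interferon genes were higher in TKO dendritic-like cells, 18 of 20 tested (median log2 0.67, camera adjusted p = 2.9e-10, and adjusted p = 0.56 with an estimated correlation), and fry gave an adjusted p of 0.048. Adjusted over the list alone 5 rose, against 0 over all genes tested, among them Isg15, a ubiquitin-like interferon-induced protein (0.82 ± 0.16). MHC class I presentation genes were higher in 15 of 16 (camera adjusted p = 9.1e-05, adjusted p = 0.66 with an estimated correlation). G2 and M phase genes were lower in 7 of 7 (camera adjusted p = 1.4e-05, adjusted p = 0.78 with an estimated correlation), and 4 fell adjusted over the list alone, against 0 over all genes tested, such as the proliferation marker gene Mki67 (-0.87 ± 0.32). Each of these 3 camera calls was kept without each library in turn. S phase genes were lower in 13 of 15 (camera adjusted p = 0.012, adjusted p = 0.78 with an estimated correlation, 0 adjusted over the list alone). Markers of other cells in this class stood at 2908 and 3250 CPM in DKO and 2588 and 2668 in TKO for monocytes, 1485 and 1182 against 1157 and 1065 for macrophages, and 56.8 and 37.2 against 30.8 and 12.4 for smooth muscle. Without TKO replicate 1 the camera adjusted p for S phase was 0.85, and without DKO replicate 1 it was 0.085.

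Other shares were also added after the data were seen. T-like cells with a UMI of Trdc, a gene of gamma-delta T cells, made up 31.6% and 23.7% in DKO and 19.9% and 16.3% in TKO, and those with a Cd4 UMI 29.5% and 24.9% against 23.3% and 35.5%. Neutrophil-like cells had a Trdc UMI in 0.45% to 1.47% of cells and a Cd4 UMI in 0% to 0.467%, and neither share was thinned.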
